A study of Homo sapiens with 2 samples.

How the data were processed

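Expression was measured in 2 MCF-7 cultures, 1 with an shGFP and 1 with an shRAD21 lentivirus, on 1 whole-transcript GeneChip array each, per the labels. Total RNA was extracted with a column kit and the sense cDNA was fragmented and end-labelled with biotin, per the labels' protocols. The summarisation and normalization of the arrays are not given in the sources used here. The deposited values are taken to be log2 values, 1 per probe set and array. That scale was inferred from the values, because they reach 13.15 and 13.16, above the natural log of the highest signal a 16-bit scanner can record (11.09) and below its log2 (16.0). The quantiles of the arrays were nearly equal, with a median gap of 0.02 and a largest gap of 0.15 between sorted columns, so the arrays were treated as already normalized between themselves. Exactly equal values on both arrays occurred in 3496 probe sets (6.52%), for a reason that is not given. No background or detection values were used here, so a dim value cannot be told from background.

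Genes were named through the platform annotation table given with the data, with symbols updated by Entrez identifier through a gene table of assembly GRCh38.p14. Of 53617 probe sets, 16098 named 1 gene, none named several and 37519 carried no gene name in that table. The latter entered no comparison of genes. Where a gene had several probe sets (779 of 14884 genes), the one with the highest mean over both arrays gave the gene value. Chromosomes and gene order come from the gene table, and no coordinates are printed because the files name no genome build.

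The main quantity was the difference shRAD21 minus shGFP of the log2 values. A gene passed the brightness filter if the higher of its values was at or above the median of all values (3.68), and genes differing by at least 1 (2-fold) were counted. With 1 array per group no test was possible, and no p-value is given. The words higher and lower compare these arrays only, and clonal, culture and array differences are included in every value. Single cells were selected and cultured, per the labels, but whether each array holds the offspring of 1 cell or of several is not stated. For each of 29 gene lists, fixed before the data were examined, the median difference of all measured members was set against 10000 random lists of equal size, drawn with the same number of genes in each of 20 brightness bins. A percentile under 2 or over 98 was described as apart from random lists. A minimum of 3 measured members for a median was chosen after the data were seen, and 26 lists met it. Of 878 listed genes 476 were measured under a name. The same procedure with 2000 random lists was applied to chromosomes, leaving out chromosome Y.

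The genes named in the text follow a rule fixed before the data were examined. They are RAD21, TGFB1, ITGA5, CDH1 and VIM; the 12 genes with the highest and the 12 with the lowest difference among those passing the filter; and up to 4 members of each list with the largest difference in size among those passing it. Genes outside the rule are marked as named after their values were seen.

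Alternatives comprised no brightness filter or one at the 75th percentile, the mean of a gene's probe sets, removal of the brightness-dependent trend by lowess (fraction 0.3), equal array medians, a floor at the 20th percentile, the mean in place of the list median, and 5 brightness bins. Filters of list members on the mean of both arrays and, for the mesenchymal and basal lists, on either array alone were added after the data were seen. A value without a test was regarded as moved when it shifted by 0.1 or more. The counting and list procedures were tested on simulated data with the brightness-dependent spread of the real genes (14884 genes). Of genes changed by 1.5 on the log2 scale 94.0% were recovered, and all of those changed by 3 were, while 0.64% of unchanged genes were counted. Of random lists 3.6% were called apart, and of lists with 10 or more genes shifted by -0.4, 95.5% were. The simulated noise was normal, with a spread taken from the bulk of the real differences, which already mix array noise and differences between the cultures. It holds no heavy tails, so 0.64% is not the share of false counts among the real genes. The noise was also drawn independently for each gene, so 3.6% is not the rate for lists whose members vary together. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.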

Results

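The data compared the transcriptome of MCF-7 cells carrying a short hairpin RNA against RAD21 with that of MCF-7 cells carrying a control hairpin against green fluorescent protein (GFP). MCF-7 is a luminal, oestrogen receptor-positive human breast cancer line, and RAD21 encodes the kleisin subunit that closes the cohesin ring. Hairpins were delivered by lentivirus with puromycin selection, and selected single cells were expanded for 30 days. Biotin-labelled cDNA from total RNA was hybridised to a whole-transcript GeneChip array, giving 53617 probe-set values per array. There was 1 array in the shGFP group and 1 in the shRAD21 group, so no difference below has a replicate check, a standard error or a p-value, and the number of arrays limits the precision. All differences are shRAD21 minus shGFP on the log2 scale, and all folds come from them. Of the probe sets, 16098 named 1 gene each, covering 14884 genes. Of these genes, 10975 (73.7%) passed the brightness filter, with at least 1 of their values at or above the median of all probe sets (3.68). The median value was 3.67 on the shGFP array and 3.68 on the shRAD21 array. The arrays correlated across probe sets (Pearson's r = 0.97), although genes are not independent replicates.

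RAD21, the targeted gene, was measured by a single probe set. Its value was 6.42 on the shGFP array and 4.92 on the shRAD21 array, a difference of -1.50 or 2.83-fold lower expression. Only 0.61% of the genes passing the filter had a lower difference. The 25 tested genes on each side of RAD21 on chromosome 8 had a median difference of 0.00. Of the 19 measured cohesin subunits and regulators, 16 passed the filter, and RAD21 was the only one that differed at least 2-fold. The cohesin acetyltransferase gene ESCO2 (-0.92) and the separase gene ESPL1 (-0.83), both expressed with the cell cycle, were the next lowest. The meiotic kleisin gene REC8 was higher (0.77). The list median was 0.10, at the 91.2nd percentile of 10000 random lists of equal size and brightness.

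VCAN, IGFBP5, MMP13 and CLDN1 were among the genes with the highest differences in shRAD21, and CEACAM5, CXCL10, SOX2 and AGR2 among those with the lowest. In all, 247 genes were at least 2-fold higher and 231 at least 2-fold lower, which together were 4.36% of the genes passing the filter. At least 4-fold differences were seen for 49 higher and 31 lower genes, and at least 8-fold differences for 14 higher and 12 lower genes. Of the 478 genes that differed at least 2-fold, 444 are protein coding. The standard deviation of the differences over all passing genes was 0.50, which includes both array noise and real differences.

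**Figure D1:**
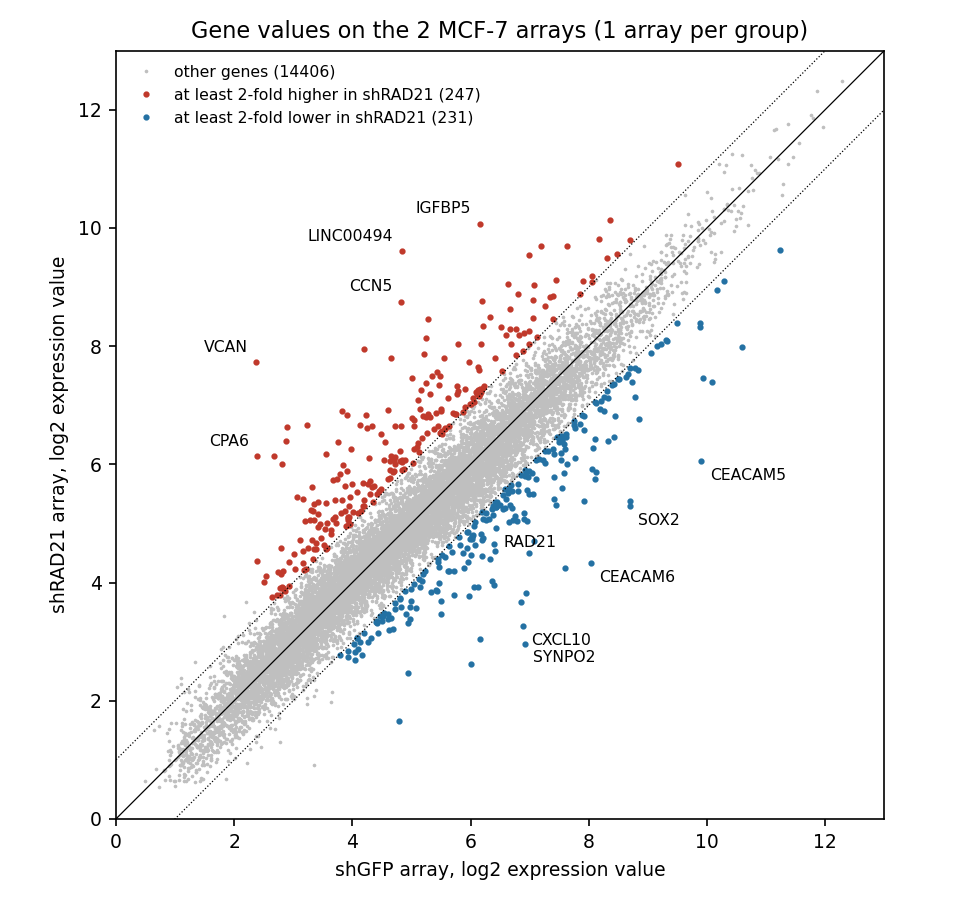
Gene values on the shGFP array (x axis) against the shRAD21 array (y axis), both log2 expression values, for 14884 genes on 1 array per group. Red points are the 247 genes at least 2-fold higher and blue points the 231 at least 2-fold lower in shRAD21 among genes passing the brightness filter; the solid line marks equal values and the dotted lines 2-fold differences, with RAD21 at 6.42 and 4.92.

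By the brightest probe set of each gene, the highest difference was that of VCAN, the matrix proteoglycan versican, at 2.37 on the shGFP array and 7.73 on the shRAD21 array (difference 5.36). A second, dimmer VCAN probe set also gave a higher value, by 1.60, and with the mean of both (3.48) VCAN lay below CCN5, IGFBP5, CPA6, IGFL1, MMP13 and CLDN1, whose differences ran from 3.52 to 3.93. The non-coding RNA gene LINC00494 followed (4.78 by its brightest probe set and 0.66 by the other). CCN5, a matricellular protein gene, was 15.2-fold higher, as was IGFBP5, which encodes an insulin-like growth factor binding protein. The carboxypeptidase gene CPA6 was 13.5-fold higher, as was IGFL1, and the collagenase gene MMP13 was 13.3-fold higher. CLDN1, a tight junction claudin, was 11.5-fold higher and the surface protein gene TM4SF1 10.8-fold. The actin-bundling gene PLS3 had a difference of 3.46. The neuropeptide Y receptor gene NPY1R and the adhesion molecule gene CADM1 were each 9.1-fold higher, and a second CADM1 probe set gave 1.32. The shGFP values of VCAN, CPA6, MMP13, CLDN1, PLS3, TM4SF1 and CADM1 lay below 3.68, where a value cannot be told from background, so the sizes and order of their differences are uncertain.

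The lowest difference was that of SYNPO2, an actin-associated protein gene, at 6.92 on the shGFP array and 2.97 on the shRAD21 array (difference -3.96). CEACAM5 and CEACAM6, neighbouring and related adhesion molecule genes, were 14.4-fold and 13.1-fold lower, and array probes can read such relatives together. The chemokine genes CXCL10 and CCL22 were 12.3-fold and 10.2-fold lower. SOX2, a pluripotency transcription factor gene, was 10.6-fold lower, from 8.70 to 5.29. The ephrin receptor gene EPHA3 was 10.5-fold lower and the adhesion molecule gene NCAM2 had a difference of -3.33. SULF1, a heparan sulphatase gene, was 9.05-fold lower and the adhesion gene FLRT3 8.73-fold lower. The pseudogene transcript ANKRD62P1-PARP4P3 had a difference of -3.14. AGR2, a secretory-pathway disulphide isomerase gene typical of luminal cells, had a difference of -3.11. The shRAD21 values of SYNPO2, CXCL10, EPHA3, ANKRD62P1-PARP4P3 and AGR2 lay below 3.68, with the same limit on sizes and order.

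Genes of DNA replication and mitosis were lower in shRAD21 almost throughout. All 24 measured DNA replication and S phase genes passed the filter, and 23 had a lower value and none a higher one. Their median difference was -0.87, a 1.82-fold lower level, below all 10000 random lists, whose 2nd to 98th percentiles ran from -0.26 to 0.14. Of them, 8 were at least 2-fold lower and none at least 2-fold higher. The cyclin gene CCNE2 (-1.62), the replication initiation genes MCM10 (-1.62) and CDC6 (-1.45) and the flap endonuclease gene FEN1 (-1.19) led the list. Of the 31 measured mitotic and G2/M genes, 30 had a lower value, with a median of -0.58, also below all random lists. The 4 that were at least 2-fold lower were the checkpoint gene MAD2L1 (-1.19), the kinase gene PLK1 (-1.18), the cyclin gene CCNA2 (-1.15) and the kinase gene AURKB (-1.08). Named after their values were seen, CDK1 was the only higher one, at 0.08, and the proliferation marker MKI67 differed by -0.18.

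DNA damage response and recombination genes were lower as well, with a median of -0.54 over 21 genes, below all random lists. Of these, 16 had a lower and 5 a higher value, and 1 was at least 2-fold lower. The lowest were RAD51AP1 (-1.03), RAD54L (-0.83), the BRCA2 partner gene PALB2 (-0.80) and the exonuclease gene EXO1 (-0.69). The highest of the 5 higher genes, named after their values were seen, were TP53BP1 (0.48) and NBN (0.28). The p53 target genes as a list did not stand apart (median 0.03 over 14 genes, 76.4th percentile). GDF15, a stress-induced cytokine gene in that list, was 5.54-fold lower, whereas TP53I3 (0.77), RRM2B (0.43) and SESN2 (-0.42) differed less than 2-fold.

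**Figure D2:**
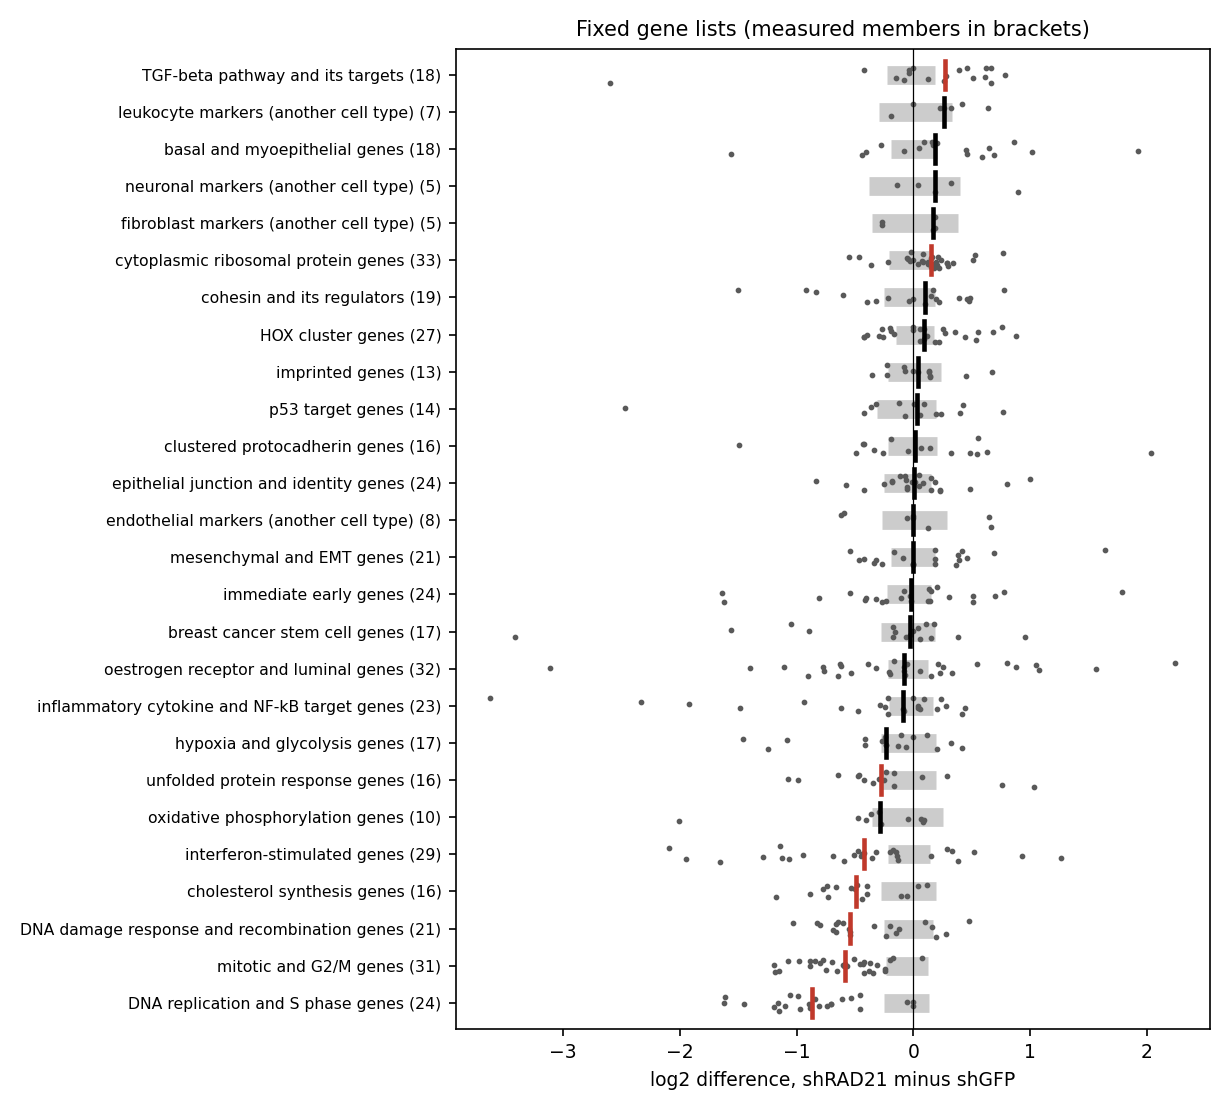
Log2 difference, shRAD21 minus shGFP (x axis), of the measured members (dots) of 26 gene lists fixed before the data were examined, with list medians as vertical bars (red where outside the 2nd to 98th percentiles of random lists, shown in grey). The DNA replication list lies lowest at -0.87 and the TGF-beta list highest at 0.27.

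Interferon-stimulated genes were also lower in shRAD21. The median over 29 measured genes was -0.42, a 1.34-fold lower level, below all random lists. Of these genes, 22 had a lower and 7 a higher value, and 7 were at least 2-fold lower. The antiviral genes OASL (-2.09), HERC5 (-1.94), IFIT2 (-1.66) and RSAD2 (-1.29) were the lowest. The list was not uniform. BST2, which encodes the virus tetherin and was named after its value was seen, was at least 2-fold higher (1.26), and IFI44L, named likewise, had a difference of 0.93. Inflammatory cytokine and NF-kB target genes had a median of -0.09 (23 genes, 19.5th percentile) and a mean of -0.47. Only 4 of their 17 genes passing the filter differed at least 2-fold, and all 4 were lower chemokine genes. These were CXCL10 (-3.62), CXCL11 (-2.33), CCL5 (-1.93) and CCL20 (-1.48). The shRAD21 values of CXCL10 (3.27) and CCL20 (3.21) lay below 3.68, so the sizes of their differences are uncertain. Of the antigen presentation genes only B2M (-0.23) and TAPBP (0.27) carried a name here, and both differed less than 2-fold. A second B2M probe set gave 0.14, and the mean of both was -0.04, so B2M had no settled direction.

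Epithelial junction and identity genes did not differ as a list. None of the 24 measured genes differed at least 2-fold, 12 had a higher and 12 a lower value, and the median was 0.00 (72.0th percentile). The tight junction scaffold gene TJP1 was 1.99-fold higher. The next largest differences were those of the lipid synthesis gene CDS1 (-0.83), the repressor gene OVOL2 (0.80) and the junction gene MARVELD3 (-0.58). EPCAM, named after its value was seen, differed by -0.06. Of the 21 measured mesenchymal and epithelial-mesenchymal transition genes, 12 passed the filter, and only the matrix glycoprotein gene THBS1 differed at least 2-fold (8.17 against 9.81, 3.12-fold higher). The matrix metalloproteinase gene MMP14 differed by 0.69, fibronectin FN1 by -0.54 and the transcription factor gene SNAI1 by -0.46. The shGFP value of MMP14 (3.21) lay below 3.68, so the size of its difference is uncertain. VIM, the mesenchymal intermediate filament vimentin, had a value of 4.57 on the shGFP array and 5.03 on the shRAD21 array (difference 0.46), and its 2 other probe sets gave 0.22 and -0.12. The mesenchymal list median was 0.00 over all measured members (48.9th percentile). Over its brighter members it depended on the array that chose them, from 0.05 (75.5th percentile) by the shGFP value to 0.37 (99.25th percentile) by the shRAD21 value, settings chosen after the data were seen. TGFB1, ITGA5 and CDH1 had no probe set named here and were not analysed here, nor were the integrin subunits.

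Of 30 listed genes of the TGF-beta pathway and its targets, 18 were measured, with a median of 0.27 (1.21-fold higher). That median lay at the 99.8th percentile of random lists. No TGFB ligand gene and no TGFBR receptor gene was measured. Of the 18 genes, 11 had a higher and 6 a lower value. None of them was at least 2-fold higher. LTBP2, which encodes a latent TGF-beta binding protein, differed by 0.78, the SMAD corepressor gene SKIL by 0.67 and the co-receptor gene ENG by 0.66. BAMBI, a decoy receptor that opposes TGF-beta signalling, was 6.05-fold lower, from 10.59 to 7.99. Named after their values were seen, SMAD2 (-0.04), SMAD3 (-0.15) and SMAD4 (-0.04) were not higher. The list mixes genes that promote and oppose the signalling, so its median gives no direction of pathway activity. With the mean in place of the median the list stood at 0.11 (88.3rd percentile). A second LTBP2 probe set had equal values on the arrays. Basal and myoepithelial genes had a median of 0.19 (18 genes, 97.1st percentile). Over brighter members it ran from 0.21 (95.2nd percentile) chosen by the shGFP value to 0.46 (99.7th percentile) by the shRAD21 value, settings likewise chosen after the data were seen. With the mean in place of the median it was 0.25 (98.9th percentile). The annexin genes ANXA3 (1.93) and ANXA1 (1.01) were at least 2-fold higher, and the receptor gene MET differed by 0.86. The shGFP value of ANXA1 (2.93) lay below 3.68, so the size of its difference is uncertain. The surface glycoprotein gene CD44 was 2.95-fold lower.

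Oestrogen receptor and luminal genes differed in both directions. Of 30 genes passing the filter, 4 were at least 2-fold higher and 3 at least 2-fold lower, and the median over the 32 measured genes was -0.08 (33.2nd percentile). The survival gene BCL2 was 4.74-fold higher and the scaffold gene PDZK1 2.96-fold higher, whereas AGR2 was 8.65-fold lower and the receptor kinase gene RET 2.63-fold lower. Named after their values were seen, ESR1, which encodes oestrogen receptor alpha, differed by -0.53, its target GREB1 by 0.88 and the progesterone receptor gene PGR by 0.80. Breast cancer stem cell genes had a median of -0.03 (17 genes, 51.8th percentile) and a mean of -0.33 (0.7th percentile). The 3 members that differed at least 2-fold were all lower, namely SOX2 (-3.41), CD44 (-1.56) and the Notch ligand gene JAG1 (-1.05), while NOTCH2 differed by 0.96.

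Among metabolic and stress lists, cholesterol synthesis genes stood lowest, with a median of -0.49 over 16 genes, 14 of them lower (0.02nd percentile). The sterol transfer gene STARD4 was 2.26-fold lower, INSIG1 differed by -0.89, HMGCS1, which encodes the synthase before the rate-limiting reductase, by -0.77, and MSMO1 by -0.74. Unfolded protein response genes had a median of -0.28 (16 genes, 1.86th percentile), with DDIT3 at -1.07 and TRIB3 at -0.99 but ASNS at 1.03 and DDIT4 at 0.76. That list lay only narrowly outside the range of random lists, and it lay within it under 3 alternatives. The shRAD21 values of STARD4 (2.74) and DDIT3 (3.66) lay below 3.68, so the sizes of their differences are uncertain. Hypoxia and glycolysis genes had a median of -0.24 (17 genes, 4.08th percentile). HK2, a hexokinase gene, was 2.75-fold lower, NDRG1 2.37-fold and ANGPTL4 2.12-fold, and TPI1 differed by -0.42. Oxidative phosphorylation genes had a median of -0.29 (10 genes, 5.02nd percentile), with COX6C 4.03-fold lower and CYC1 (-0.48), COX7B (-0.41) and UQCRC2 (-0.36) under 2-fold. Cytoplasmic ribosomal protein genes stood slightly higher, with a median of 0.15 over 33 genes, 24 of them higher (98.8th percentile). With the mean in place of the median that list stood at 0.12 (94.6th percentile), within the range of random lists. None differed at least 2-fold, and the largest differences were those of RPL19 (0.77), RPL32 (-0.55), RPS27 (0.52) and RPL12 (0.51). A second RPL19 probe set gave 0.45.

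The remaining lists lay within the range of random lists. Immediate early genes had a median of -0.02 (24 genes, 54.3rd percentile), with FOS 3.44-fold higher and the phosphatase genes DUSP4 and DUSP5 3.11-fold and 3.09-fold lower. IER3 differed by -0.81 by the brightest of its 11 probe sets, and the others gave -0.81 to -0.28. Second probe sets of FOS and DUSP5 gave 0.47 and -0.35. The shRAD21 value of DUSP5 (3.32 by its brightest probe set) lay below 3.68, so the size of its difference is uncertain. HOX cluster genes had a median of 0.09 (27 genes, 83.2nd percentile) and none differed at least 2-fold, with HOXC4 (0.88), HOXD12 (0.76), HOXC11 (0.68) and HOXB9 (0.55) the furthest. Of 53 listed clustered protocadherin genes 16 were measured, all of them PCDHB genes, with a median of 0.01 (60.3rd percentile). The rest of the listed protocadherins carried no name here, so the median says nothing about them. In this family of closely related genes PCDHB6 was 4.09-fold higher and PCDHB5 2.82-fold lower, and PCDHB9 (0.63) and PCDHB10 (0.55) differed less than 2-fold. Imprinted genes had a median of 0.04 (13 genes, 62.6th percentile), with MEST at 0.67 and PLAGL1 at -0.36. No replication-dependent histone gene was named here.

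Among markers of other cell types, no gene passing the filter was at least 2-fold different. The median was 0.17 for 5 fibroblast markers (79.3rd percentile), where THY1 differed by 0.18 and FBLN1 by 0.17. It was 0.00 for 8 endothelial markers (48.7th percentile), with ERG at 0.65 and CLDN5 at -0.62. It was 0.26 for 7 leukocyte markers (94.7th percentile), with LAPTM5 at 0.64 and TYROBP at 0.33. It was 0.18 for 5 neuronal markers (82.7th percentile), with MAP2 at 0.90 and GAP43 at 0.32. In all, 8 of the 26 lists with a median lay below the 2nd or above the 98th percentile, against 1.04 expected by chance for unrelated genes. Members of a pathway vary together and some lists share members, so this count overstates the number of independent departures.

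Median differences of whole chromosomes were small but unequal. Of the 23 chromosomes compared (1 to 22 and X), 11 had a median difference outside the 2nd to 98th percentiles of 2000 random lists. Random lists draw scattered genes, whereas neighbouring genes differed the same way (below). Their ranges may therefore be too narrow for whole chromosomes and the count of 11 too high. Chromosome 6 was lowest, at -0.15 over 760 genes and -0.23 over the 544 passing the filter. Chromosome 14 was highest, at 0.15 over 478 genes, followed by chromosome 19 at 0.10 over 1081 genes. Chromosome 13 stood at -0.09 over 313 genes. Chromosome 8, which carries RAD21, had a median of 0.00 over 547 genes.

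**Figure D3:**
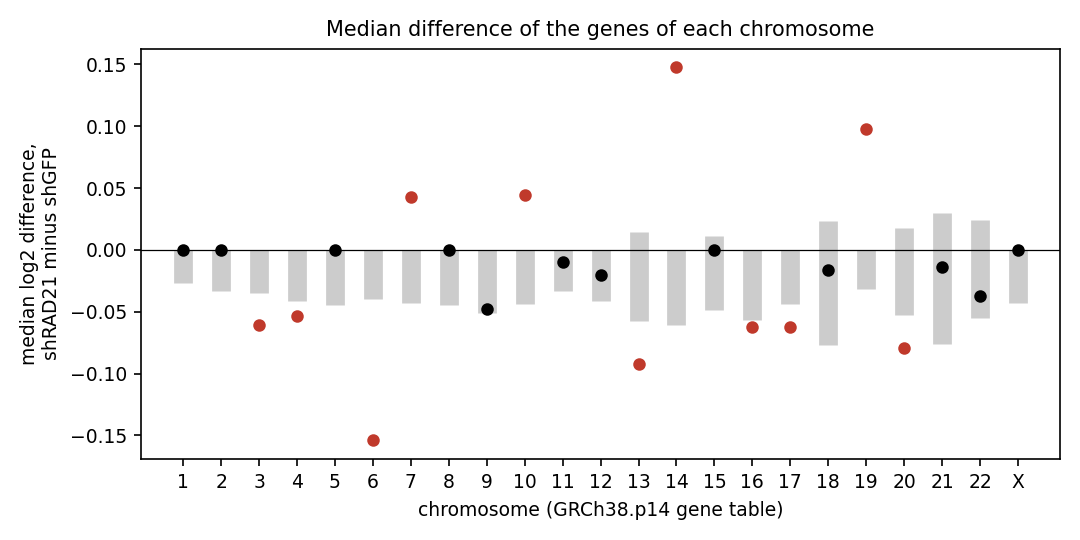
Median log2 difference, shRAD21 minus shGFP (y axis), of all genes measured on each chromosome (x axis), with the 2nd to 98th percentiles of 2000 random lists of equal size and brightness in grey and chromosomes outside them in red. Chromosome 6 lies lowest at -0.15 and chromosome 14 highest at 0.15.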

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

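Signal also lay in probe sets that the comparisons of genes did not use. Among 16751 probe sets without a gene name here that passed the brightness filter, 502 were at least 2-fold higher and 526 at least 2-fold lower in shRAD21. The highest were probe sets 17020846 (4.26 against 9.60) and 16920006 (6.58 against 11.15). The lowest were probe sets 16697400 (8.28 against 2.81) and 17120882 (7.14 against 2.98).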

How the results depend on the processing

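No paired analysis was possible because each group holds 1 array, and no array could be left out. The alternative for probe sets naming several genes gave no value because none did. RAD21 stayed between -1.47 and -1.51. The count of genes at least 2-fold higher ran from 194 (filter at the 75th percentile) to 261 (no filter), and that of lower genes from 186 to 249 under the same settings. Of 158 alternative list values, 138 kept their description, and 5 of the 8 lists that stood apart did so under every alternative, namely the replication, mitotic, DNA damage, interferon and cholesterol lists. With the mean in place of the median, the TGF-beta list (0.11), the unfolded protein response list (-0.21) and the ribosomal list (0.12) no longer stood apart. The basal (0.25), stem cell (-0.33) and cytokine (-0.47) lists then did. The cohesin (-0.074), p53 (-0.11) and fibroblast (-0.0002) lists changed sign, and the mesenchymal list shifted to 0.11. Beyond the weight a mean gives to extreme members, the cause was not tested. Over genes passing the brightness filter only, the mesenchymal (0.28) and basal (0.46) lists stood apart and the imprinted list moved to 0.14. Filters chosen after the data were seen gave 0.28, 0.33 and 0.14 for these lists by the mean of both arrays, where the fibroblast list had too few members. The mesenchymal and basal lists were at 0.37 and 0.46, both apart, by the shRAD21 value, but at 0.05 (75.5th percentile) and 0.21 (95.2nd percentile), not apart, by the shGFP value, so whether they stand apart depends on the filter. The unfolded protein response list (-0.28) no longer stood apart with the mean of a gene's probe sets (2.18th percentile) or with 5 bins (2.1st percentile). The same 11 chromosomes stood apart over genes passing the filter only. With the trend removed by lowess, a setting chosen after the data were seen, 11 did again, but chromosome 16 no longer (2.65th percentile) and chromosome 1 newly (99.2nd percentile). Of 124 named genes besides RAD21, 10 moved by at least 0.1, all with the mean of their probe sets, among them VCAN to 3.48, LINC00494 to 2.72, CADM1 to 2.25, FOS to 1.13, DUSP5 to -0.99 and B2M to -0.04. Signal over background was not available, so differences of dim genes cannot be bounded.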

Other observations

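The symbol families, the split of chromosome 6, the chromosome 19 test and the growth-state test were chosen after the results were seen; the other tests below were set before. Several gene families, some of which share members with the fixed lists, also stood together. Genes sharing a symbol stem, with at least 8 members passing the filter, formed 167 families, of which 19 lay outside the 2nd to 98th percentiles of random lists against 6.68 expected by chance. Mitochondrial ribosomal protein genes were lower, with medians of -0.46 over 52 MRPL genes and -0.29 over 26 MRPS genes, while the cytoplasmic RPL family stood at 0.15 over 56 genes, related pseudogenes included. The TIMM genes of mitochondrial protein import (median -0.37, 13 genes) and the EXOSC genes of the RNA exosome (-0.42, 10 genes) were lower. The 11 genes with the MCM stem, most of them replicative helicase subunits and also in the fixed replication list, had the lowest median of the 167 families, at -0.97. Annexin genes were higher (median 0.26, 18 genes with the ANXA stem), 3 of them at least 2-fold, including ANXA3 and ANXA1 of the basal list. Matrix metalloproteinase genes, with MMP14 of the mesenchymal list among them, had a median of 0.19 (20 genes).

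Zinc finger genes with the ZNF stem had a median of 0.08 over 491 genes, and 11 of them were at least 2-fold higher and none at least 2-fold lower. A candidate explanation is their position on chromosome 19, where most clusters of such genes lie. The 231 ZNF genes on chromosome 19 had a median of 0.17, with 0.12 to 0.24 as the 2nd to 98th percentiles of resampled genes. The 260 on other chromosomes had a median of -0.045 (-0.10 to 0.00), so the shift of the family was that of its chromosome 19 members. Other genes of chromosome 19 had a median of 0.07 (0.04 to 0.10), so the chromosome stood higher beyond its ZNF genes. The resampling treated genes as independent, whereas neighbouring genes differed the same way (below), so these intervals may be too narrow. Array probes can also read clustered related genes together, so whether the ZNF genes exceed the rest of the chromosome is not settled.

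The first pattern weighed is the 478 genes at least 2-fold different. Broad copy number differences between the selected cells that shift neighbours by at least 0.3 do not account for most of them. A stretch of neighbours shifted the same way by that much held 6.07% (29 genes), below the 20% bound set beforehand. That share exceeds the 3.36% of all tested genes in a stretch shifted by that much in either direction. With so few genes in such stretches the bound was easily met, and smaller broad shifts were not covered by this test. The brightness-dependent trend left between these arrays was small, from -0.15 to 0.03, so its removal could change few calls. After it 96.0% of the 478 genes stayed at least 2-fold different, a share that the small trend made likely in advance. A trend of that size is too small to give 2-fold differences by itself. For admixed fibroblasts, the median of the 5 markers measured differed by 0.17, and only 2 of them passed the brightness filter. DCN was at 2.23 and 1.96 and LUM at 2.23 and 2.42 (both named after their values were seen). Such dim values cannot be told from background, so the markers gave no sign of fibroblasts but cannot exclude a small admixture. Copy number changes of single genes, differences between the selected cells unrelated to the hairpin (whether each culture is 1 clone is not stated), hairpin off-targets and single-array noise stay open and were not tested. The loss of RAD21 itself is the biological explanation that the design names, and with 1 array per group it stays untested.

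The second pattern is that neighbouring genes differed the same way. Adjacent genes had correlated differences across genes (r = 0.14 over 10947 pairs). Without pairs sharing a symbol stem r was 0.13, outside the -0.03 to 0.03 of 1000 random gene orders. That argues against related genes with a shared stem, read by shared probes, as the whole source. Overlapping genes and relatives with different stems were left in, so shared signal between those was not tested. Genes 20 places apart kept 37.7% of the adjacent correlation without shared stems (r = 0.05), which lies between the bounds set beforehand. At 50 places r was 0.06, no lower, which goes towards a broad part. Still, a broad copy number difference and a local effect cannot be told apart for the pattern as a whole. Stretches were picked where the median of a gene's neighbours was shifted by at least 0.3, so their own medians partly follow from that choice. Long stretches with low medians lay on chromosomes 13 (71 genes, -0.38) and 4 (47 genes, -0.32). On chromosome 6 lay such stretches of 55 genes (-0.47), 49 genes (-0.40) and 40 genes (-0.39). A shorter stretch on chromosome 14 stood higher (11 genes, 0.44). The 5 successive parts of chromosome 6, the only one split and chosen because its median was lowest, had medians from -0.36 to -0.12. That split decides nothing about copy number. After each gene's stretch median was subtracted, r was 0.07 for adjacent genes and -0.02 at 20 places, so a local part may remain, and whether it relates to cohesin was not tested.

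The third pattern is the lower level of replication and mitotic genes. Of 55 genes in either list, 53 were lower. Removing the brightness trend left the mitotic list, the higher of both, at -0.52. Subtracting each member's stretch median left a pooled median of -0.64 (quartiles -0.88 and -0.43). The trend was small (-0.15 to 0.03), as were the median stretch values of the replication (-0.05) and mitotic (-0.04) lists. Neither removal could therefore have changed the medians much. A trend or broad shifts of that size are too small to account for the lower level. Copy number changes of single genes were not covered. A different growth state of the 2 cultures at harvest may give the same picture, with 53 of 55 genes lower, and cannot be told apart from the hairpin because each culture is 1 array.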
